A study of Homo sapiens with 6 samples.

How the data were processed

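The series holds 6 arrays with 2 colours each, made with RNA of HaCaT cells that had been treated with TGF-beta1 or left untreated in serum-free medium. Per the labels, cells were grown with serum, washed, and treated with 5 ng/ml TGF-beta1 or kept without it for 1 h, 4 h or 12 h. RNA was extracted with TRI reagent, cleaned on columns and labelled directly, untreated RNA with Cy3 and treated RNA with Cy5 on all arrays, per the labels' protocols. No array had the dyes exchanged. The arrays were cDNA arrays read with Quantarray and analysed with Avadis, per the series' design text. The deposited values are log2 ratios of treated over untreated RNA, per the labels and design text, and the authors' background correction, normalization, spot filters and software versions are not given in the sources used here. Array medians lay between 0.01 and 0.02 and standard deviations between 0.286 and 0.442, so the ratios look centred per array, by a method that remains unknown. The direction follows from the dyes and the design text. Single-channel intensities were not used here, so signal over background could not be assessed. The design text also names lung epithelial cells, which are not analysed here.

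The table has 19200 rows, of which 17800 had a value on all arrays, and 1.77% of all cells were empty. Rows were named through the platform annotation, which lists 9566 rows with 1 gene symbol, 471 with several and none for 9163, and unlisted rows are unnamed here rather than without a gene. Of the rows with 1 symbol, 9561 were found by gene ID in the reference gene table and 5 were not, and no symbol changed. Rows of the same gene were averaged, which applied to 2010 genes with more than 1 row, and rows without a single symbol were kept on their own. Which rows of a gene had a value could differ between times. A feature was tested where it had a value on both arrays of each time compared.

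Groups and Exp numbers come from the sample titles, and 0 columns were left without a sample. One model with a mean for each time was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the times share an estimate of the spread. Each time was tested against 0, and the 3 differences between times were tested in the same model. Tests were two-sided, and features at a Benjamini-Hochberg adjusted p under 0.05 were called. Features at least 1.5-fold higher or lower on both arrays of a time were counted beside the number that independent arrays would share. Before the data were examined, 34 gene lists were fixed, covering pathways, structural gene groups and markers of other cell types. The 31 lists with at least 5 measured genes were tested with cameraPR on limma's moderated statistics at a preset correlation of 0.01, with camera at an estimated correlation and with fry as alternatives. The list tests on differences between times were added after the data were seen.

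Genes were named by a rule fixed before the data were examined. For each time it takes the 10 higher and 10 lower genes with the largest log2 ratio among those that passed with the same sign on both arrays, 14 known TGF-beta genes wherever measured, and up to 4 members of each list described. For differences it takes 5 higher and 5 lower genes, and places left open are filled by genes that did not pass, chosen by the largest smaller-array value or gap between arrays. Alternatives were other normalizations (median, equal median absolute deviation, quantile), features on all arrays, a test for each row, a fit to the arrays compared alone, a robust prior, array weights, the Exp number as a block, other fold thresholds, and each array left out. Subtracting the median of each run of 400 table rows was added after the data were seen, as was a crossed pairing of Exp numbers.

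The functions were tested on simulated data with 200 changed features for each comparison. The simulated values had the spread of these arrays but no dye effects, no trends and no correlation between genes. Of changes of 1.5-fold, 2-fold and 4-fold, 17.9%, 95.5% and 100% were called at 1 h, 20.9%, 86.6% and 100% at 4 h, and 19.4%, 88.1% and 100% at 12 h. The shares were 1.49%, 40.3% and 100% for 4 h against 1 h, 0%, 38.8% and 98.5% for 12 h against 1 h, and 1.49%, 43.3% and 100% for 12 h against 4 h. Between 2 and 9 unchanged features were called for each comparison. With no list shifted, 0 of 31 lists were called by any of the 3 list tests. In a simulation at 12 h with the 19 members of 1 list shifted by 0.5, the shifted list had an adjusted p of 1.16e-32 with the preset correlation. It was 0.323 with an estimated correlation and 0.14 with fry. The latter tests thus missed a shift among uncorrelated genes at this number of arrays. With the preset correlation 2 of 31 lists were called, so a list other than the shifted one also passed. Some fixed lists share members with the shifted one. Because genes were drawn independently, the simulation cannot show how the list tests behave where genes are correlated.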

Results

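HaCaT cells, an immortalized human skin keratinocyte line, were kept in serum-free medium with or without 5 ng/ml TGF-beta1 for 1 h, 4 h or 12 h. TGF-beta1 is a secreted cytokine that signals through SMAD transcription factors. The study asked which transcripts TGF-beta1 regulates in these cells over time. Treated and untreated RNA of the same time point were hybridised together on cDNA arrays, with 2 arrays (Exp1 and Exp2) for each time and 6 arrays in all. Each value is the deposited log2 ratio of treated over untreated RNA, so that a value above 0 means a higher level with TGF-beta1. Of 19200 rows, between 18457 and 19167 had a value on an array, and the array medians lay between 0.01 and 0.02. Rows of the same gene were averaged, which gave 16443 features, of which 6809 were named genes. Untreated RNA was labelled with Cy3 and treated RNA with Cy5 on all 6 arrays, so a ratio at a single time also holds any dye effect of the gene, whereas a constant dye effect cancels in a difference between times. The labels do not say that Exp1 and Exp2 were separate cultures, so p-values measure the spread between these arrays, which may be technical. The small number of arrays limits the precision. Errors are standard errors from limma with n = 2 arrays per time, and adjusted p-values are limma's with Benjamini-Hochberg adjustment.

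After 1 h, the transcript with the largest called rise among named genes was KLF10, a zinc finger repressor also known as the TGF-beta inducible early gene. Its log2 ratio was 1.32 ± 0.12 (adjusted p = 0.00425), a 2.50-fold higher level. VEGFA, the angiogenic growth factor, rose by 0.84 ± 0.14 (adjusted p = 0.0189), and CCN2, a matricellular protein, by 0.71 ± 0.13 (adjusted p = 0.0252). CPNE3, GPD2, CCT6A, MDFIC, TOLLIP-DT, EEF1AKMT3 and EMB completed the 10 named genes with the largest rises, at log2 ratios between 0.65 and 0.73. TGFBR2, the type II TGF-beta receptor, rose by 0.60 ± 0.14 (adjusted p = 0.0491), and SMAD5 by 0.64 ± 0.15 (adjusted p = 0.0443). The list of known TGF-beta and SMAD targets did not pass at 1 h (adjusted p = 0.225). Of its 18 measured members 3 were higher and 2 lower, COL4A1 and ANGPTL4 (-0.93 ± 0.16), and adjusted over the list alone 5 were higher and 2 lower. JUNB was at 0.37 ± 0.11 (adjusted p = 0.0769), ID2 at 0.28 ± 0.11, TGFBI at 0.25 ± 0.14, PMEPA1 and ID1 both at 0.05, and CDKN1A at -0.06 ± 0.17, and none of these passed. The 3 rows of JUNB and the 2 rows of ID2 differed from each other. SMAD7, CDKN2B, MYC and ID3 were not analysed here, and SKIL had a value on a single 1 h array.

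The 10 named genes with the largest called falls at 1 h had log2 ratios between -3.33 and -2.53. They were CEP15, CYB5D1, IFRD2, NOTCH2NLA, ATP13A5, SDCCAG8, TBC1D31, SDHC, MAN1A1 and TMX3. On 12 h Exp2 these genes lay between -0.59 and -0.08, and on 12 h Exp1 between -3.43 and -0.30. Epithelial junction genes had 3 of 12 measured members lower, among them the desmosomal cadherin DSC3 (-2.45 ± 0.35) and the gap junction protein GJA1 (-0.75 ± 0.16). Adjusted over the list alone, 2 were higher and 5 lower. The extracellular matrix list had the collagens COL8A1 (-2.03 ± 0.24), COL18A1 (-1.41 ± 0.18) and COL4A1 (-1.03 ± 0.20) lower and CCN2 higher, out of 32 members, and the counts adjusted over the list alone were the same. The fall of COL18A1 rested largely on 1 of its 2 rows, at -3.30 and -1.76 on the 1 h arrays. Its other row was at -0.32 and -0.26. The 2 rows of COL4A1 differed in size. Among oxidative phosphorylation genes, SDHC (-2.67 ± 0.32), NDUFV1 (-1.11 ± 0.17) and NDUFS7 (-0.91 ± 0.13) were lower out of 21, and 2 higher and 4 lower passed adjusted over the list alone. The 2 rows of NDUFV1 disagreed, with 1 at -2.24 and -1.85 and the other at -0.27 and -0.10 on the 1 h arrays. ACTA2, smooth muscle actin, was at -0.69 ± 0.15 (adjusted p = 0.0416).

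In all, 882 of 16232 features passed at 1 h, 152 higher and 730 lower, against 4928 with an unadjusted p under 0.05. Named genes made up 48 of the higher and 299 of the lower features. At least a 1.5-fold change in the same direction on both arrays was seen for 20 higher and 672 lower features and in opposite directions for 0, where independent arrays would give 2.66 and 98.2. None of the 31 gene lists tested with limma's cameraPR passed at 1 h (smallest adjusted p = 0.197), 3 had an unadjusted p under 0.05, and camera with an estimated correlation and fry also called 0. The marker lists of blood and immune cells, of fibroblasts and of liver, muscle and nerve had medians of -0.24, -0.03 and 0.04. The call count was 0 without 1 h Exp1, 130 without 1 h Exp2, 1803 without either 12 h array and 725 without either 4 h array (51 higher, 674 lower). With arrays set to equal spread it was 766, with 58 higher and 708 lower. With the Exp number as a block it was 328, with 11 higher and 317 lower.

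**Figure D1:**
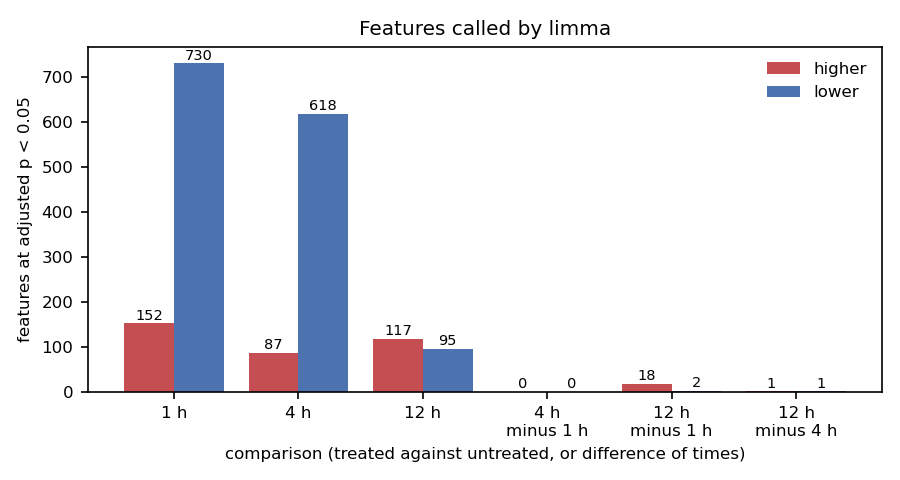
Bars give the number of features at an adjusted p under 0.05 in limma (vertical axis) for each time against untreated and each difference of times (horizontal axis), split into higher and lower. Lower calls outnumbered higher calls at 1 h (730 against 152) and 4 h (618 against 87), and at 12 h there were 117 higher and 95 lower.

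After 4 h, THBS1, which encodes the matricellular protein thrombospondin 1, stood at a log2 ratio of 2.73 ± 0.25 (adjusted p = 0.0242), a 6.62-fold higher level, after 0.20 on both arrays at 1 h. Both of its rows were above 1.9 on both 4 h arrays. PMEPA1, a known feedback inhibitor of SMAD signalling, rose by 1.17 ± 0.14, VEGFA by 1.13 ± 0.14 and CCN2 by 0.98 ± 0.13 (adjusted p = 0.0242 for each). FRMD6, CFAP69, ORMDL2, DAAM1, NET1 and SGCA were the remaining genes among the 10 largest rises, between 0.90 and 1.24. DAAM1, an actin regulator, and NET1, a RhoA exchange factor, were at 0.96 ± 0.15 and 0.93 ± 0.14, while the 2 rows of SGCA disagreed. TGFBI, a matrix protein named for its induction by TGF-beta, rose by 0.87 ± 0.14 (adjusted p = 0.0284), and KLF10 by 0.52 ± 0.12 (adjusted p = 0.0462). SKIL, a SMAD corepressor, was at 0.54 ± 0.14 (adjusted p = 0.0675), JUNB at 0.32 ± 0.11, ID1 at 0.14 ± 0.13 and ID2 at -0.05 ± 0.11, and none of these passed. CDKN1A had a value on a single 4 h array.

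The list of known TGF-beta and SMAD targets was the one list called at 4 h. It had 6 of 18 measured members higher and 0 lower, a median of 0.32 and an adjusted p of 1.96e-07 with the preset correlation. Adjusted over the list alone, 8 were higher and 2 lower. The adjusted p was 0.818 with an estimated correlation and 0.0539 with fry. In the other lists, the ubiquitin ligase SMURF2 (0.65 ± 0.13), the collagen receptor subunit ITGA2 (0.60 ± 0.12), ACTA2 (0.74 ± 0.15), the actin-binding tropomyosin TPM1 (0.69 ± 0.13) and the stress gene GADD45A (0.62 ± 0.14) rose. Lower members passed too, with 1 of 15 cytoskeletal and contractile genes. Epithelial junction genes had 2 of 12 lower, matrix proteases and inhibitors 2 of 20 and oxidative phosphorylation genes 2 of 21, each with 0 higher. Of 18 G1/S and DNA replication genes 2 were lower, ORC2 (-0.61 ± 0.12) and MCM6 (-0.55 ± 0.11), and the list did not pass (adjusted p = 0.344), with 2 lower adjusted over the list alone. Of 14 G2/M and mitosis genes 1 was lower, CKS1B (-0.84 ± 0.15), also 1 adjusted over the list alone, and that list did not pass either (adjusted p = 0.838). The CDK inhibitor CDKN1C was at -0.88 ± 0.19 (adjusted p = 0.043).

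The 10 named genes with the largest called falls at 4 h were CYB5D1, SDCCAG8, DAZAP1, DSC3, GINS3, TMX3, RPEL1, AAK1, COL8A1 and DCUN1D4, between -2.31 and -1.55. On 12 h Exp1 they lay between -2.05 and -1.05, and on 12 h Exp2 between -0.61 and -0.00. Altogether 705 of 16029 features passed at 4 h, 87 higher and 618 lower, of which 36 and 232 were named genes. On both arrays, 41 were at least 1.5-fold higher, 501 at least 1.5-fold lower and 0 opposite, where independent arrays would give 1.06 and 64.8. Lower calls at both 1 h and 4 h numbered 327, where independent lists would share 27.9, and higher calls at both numbered 11, against 0.828. The common dye orientation and the estimate of the spread that the times share can add to such overlaps. The marker lists of blood and immune cells, of fibroblasts and of liver, muscle and nerve had medians of -0.02, -0.08 and -0.02 at 4 h. The count was 0 without 4 h Exp2, 459 without 4 h Exp1, 161 without either 1 h array and 1366 without either 12 h array, and it was 1905 with arrays set to equal spread. With the Exp number as a block it was 58, with 21 higher and 37 lower.

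**Figure D2:**
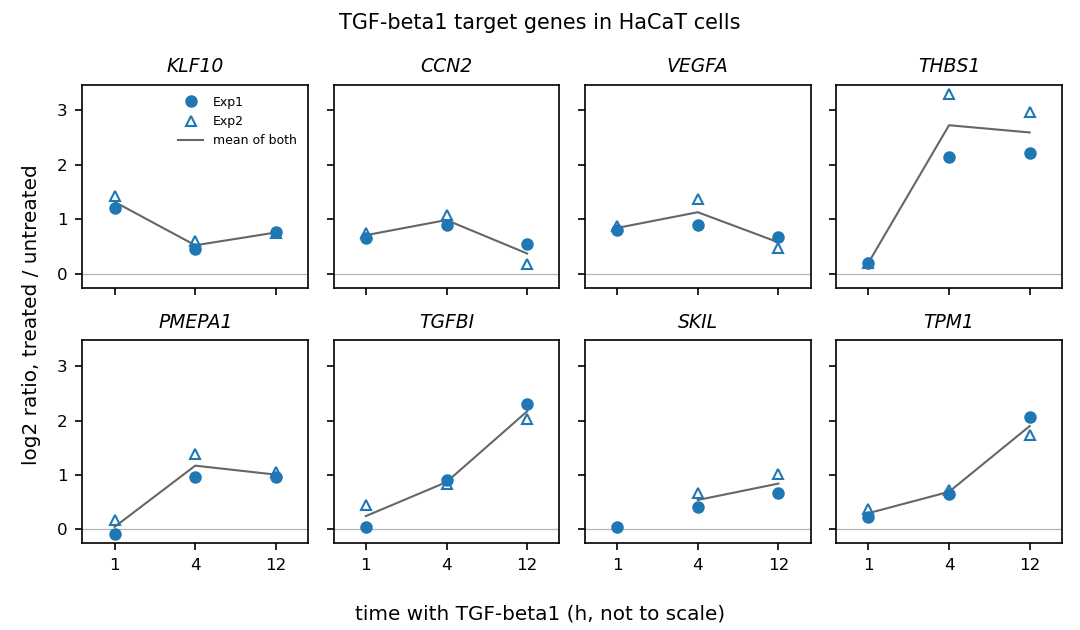
Log2 ratio of treated over untreated RNA (vertical axis) for 8 genes at 1 h, 4 h and 12 h (horizontal axis, not to scale), with a symbol for each array and a line through the mean where both arrays had a value. KLF10 was at 1.32 at 1 h and 0.52 at 4 h, THBS1 was at 2.73 at 4 h and 2.59 at 12 h, and TGFBI was at 0.87 at 4 h and 2.17 at 12 h.

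After 12 h, THBS1 had the largest called rise among named genes. It was at 2.59 ± 0.25 (adjusted p = 0.00251), TGFBI at 2.17 ± 0.14 (adjusted p = 0.000264) and fibronectin, FN1, at 1.41 ± 0.19 (adjusted p = 0.0156). TPM1 rose by 1.90 ± 0.13 (adjusted p = 0.000314), the cardiac actin gene ACTC1 by 1.57 ± 0.11 (adjusted p = 0.000387) and ACTA2 by 1.11 ± 0.15 (adjusted p = 0.016). Actin transcripts are closely alike, so a cDNA spot for ACTC1 or ACTA2 may also bind other actins. ORMDL2, a regulator of sphingolipid synthesis, rose by 2.52 ± 0.18 (adjusted p = 0.000387), COA3, a cytochrome oxidase assembly factor, by 1.63 ± 0.13, and ALDH1A3, a retinaldehyde dehydrogenase, by 1.37 ± 0.13. SELENOS and MICALL2 were at 1.16 ± 0.19 and 1.11 ± 0.12. PMEPA1 (1.01 ± 0.14), SMURF2 (0.96 ± 0.13), SKIL (0.84 ± 0.14) and KLF10 (0.76 ± 0.12) were also higher, as were CAV1, the caveolar coat protein (0.93 ± 0.11), and DUSP6, a phosphatase of ERK (0.78 ± 0.12). CCN2 at 0.37 ± 0.13, ID1 at 0.55 ± 0.13 (adjusted p = 0.0736), JUNB at 0.23 ± 0.11, CDKN1A at 0.21 ± 0.17 and ID2 at -0.15 ± 0.11 did not pass.

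The largest called fall among named genes at 12 h was that of KRT15, a keratin of basal keratinocytes, at -1.57 ± 0.17 (adjusted p = 0.00571). It rested on 1 of its 2 rows, since the other had no value at 12 h. It was followed by CUX2 (-1.43 ± 0.14), AGR2 (-1.17 ± 0.21), the kinase MAP4K5 (-1.11 ± 0.13) and ATP5MC1, a subunit of ATP synthase (-1.10 ± 0.21). SAT1, a polyamine-degrading enzyme, SHARPIN, ZC2HC1C, PTGDS and AGT lay between -0.97 and -0.83. PCNA, the sliding clamp of DNA replication, fell by 0.71 (SE 0.13, adjusted p = 0.0407), STMN1, a microtubule destabiliser, was at -0.61 ± 0.12, and the proteasome subunit PSMB6 was at -0.63 ± 0.13. The 5 rows of STMN1 differed in size.

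**Figure D3:**
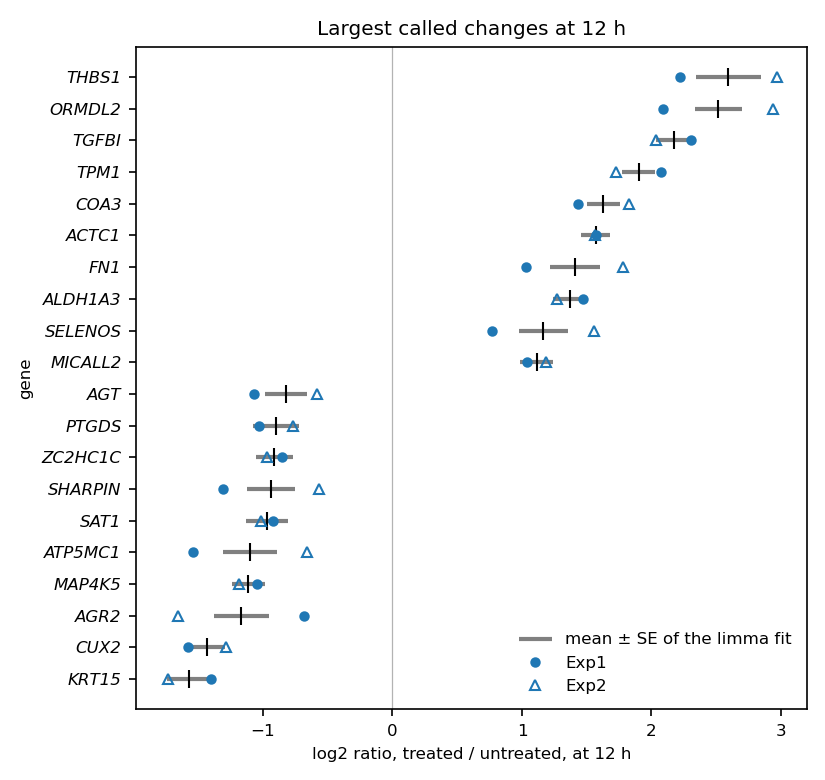
Log2 ratio at 12 h (horizontal axis) of the 10 higher and 10 lower named genes with the largest called changes (vertical axis), with a symbol for each array, a tick at the mean and a bar for the standard error of the limma fit. The means run from THBS1 at 2.59 to KRT15 at -1.57, and all 20 genes were chosen to have both arrays on the same side of 0.

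Gene lists that passed at 12 h numbered 8, with 5 higher and 3 lower. None of the 8 calls held with an estimated correlation, where the smallest adjusted p was 0.376. That test also missed a shifted list of uncorrelated genes in the simulation, so these losses cannot tell whether correlation between genes made the calls. Without 12 h Exp2 4 lists passed, and 11 did after the median of each run of 400 table rows was subtracted. The known TGF-beta and SMAD targets had 5 of 19 members higher (8 adjusted over the list alone) and 0 lower, with a median of 0.31 (adjusted p = 1.78e-10). Cytoskeletal and contractile genes had TPM1 and ACTA2 higher among 14 (4 adjusted over the list alone) and a median of 0.25 (adjusted p = 1.57e-05). Mesenchymal genes had FN1 and ACTA2 higher among 13 (3 adjusted over the list alone), with an adjusted p of 0.0173, while S100A4 was at 0.58 and vimentin, VIM, at 0.12. Cholesterol synthesis genes had a median of 0.19 (adjusted p = 0.0314) with 0 of 14 passing singly (2 adjusted over the list alone), led by HMGCS1 at 0.55, whose 4 rows differed, and SC5D at 0.46. Growth factor genes had FGFR1 (0.69 ± 0.11) higher among 18 (4 adjusted over the list alone), with an adjusted p of 0.0483, and 1 of the 2 rows of FGFR1 was near 0. Oxidative phosphorylation genes shifted down (median -0.22, adjusted p = 0.00325), with ATP5MC1 and NDUFS7 lower among 21 (4 adjusted over the list alone) and COX4I1, whose 2 rows disagreed, at -0.61. Genes of G1/S and DNA replication also shifted down (median -0.09, adjusted p = 0.0411), with PCNA lower among 18 (3 adjusted over the list alone) and MCM7 at -0.52, RPA1 at -0.56 and CCND1, which encodes cyclin D1, at -0.59. That median was -0.12 at 1 h and -0.09 at 4 h. Markers of blood and immune cells had a median of -0.24 (adjusted p = 0.0411) with 0 of 7 passing (1 adjusted over the list alone), and fibroblast markers and those of liver, muscle and nerve had medians of 0.04 and 0.03. The blood and immune list was fixed to stand for cells other than keratinocytes. Its call limits how far calls of the neighbouring lists can be read as a response to TGF-beta1. Of the 8 lists, 1 also passed for 12 h against 1 h, cytoskeletal and contractile genes (adjusted p = 4.24e-05, and 0.898 with an estimated correlation). The other 7 had an adjusted p between 0.0526 and 0.859 for that difference, which thus does not exclude a constant dye effect for them. With fry, 6 of the 8 had an adjusted p under 0.05, whereas mesenchymal genes had 0.0985 and blood and immune markers 0.28. Among lists that did not pass, extracellular matrix genes had 3 of 29 higher (5 higher and 3 lower adjusted over the list alone) and a median of 0.04 (adjusted p = 0.071, and 0.853 with an estimated correlation). After the subtraction of run medians their adjusted p was 0.00197 with the preset correlation, although their median was then -0.02. Basal and simple keratins had KRT15 lower out of 7 (adjusted p = 0.74) and epithelial junction genes had 0 of 11 passing (adjusted p = 0.403).

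**Figure D4:**
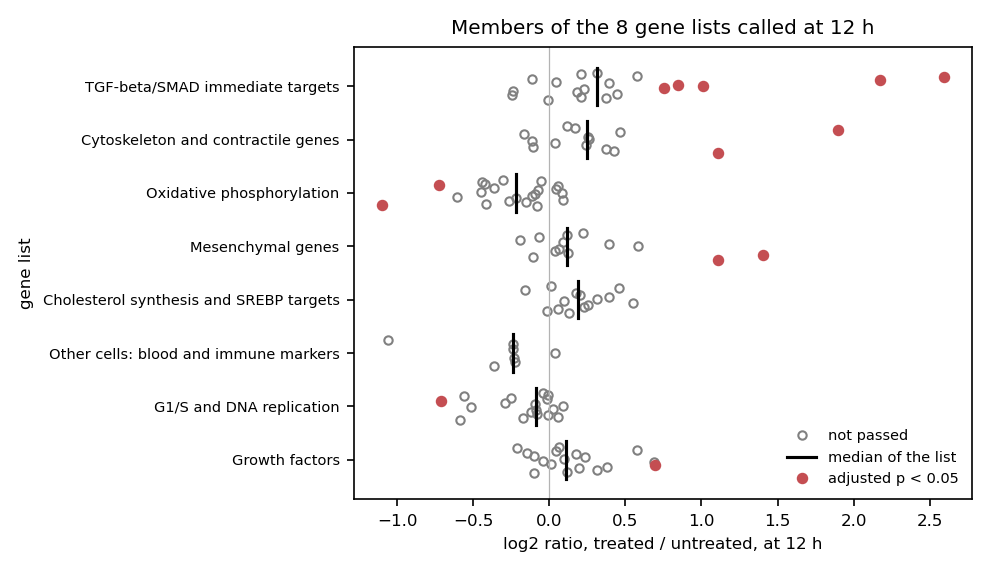
Log2 ratio at 12 h (horizontal axis) of the measured members of the 8 called gene lists (vertical axis), with filled symbols for genes at an adjusted p under 0.05 and a bar at the median of each list. The medians run from 0.31 for TGF-beta and SMAD targets to -0.24 for blood and immune markers, and most members did not pass singly.

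Across the array, 212 of 15794 features passed at 12 h, 117 higher and 95 lower, of which 46 and 33 were named genes. On both arrays 111 features were at least 1.5-fold higher, 88 at least 1.5-fold lower and 1 opposite, where independent arrays would give 4.44 and 19.1. Higher calls shared by 4 h and 12 h numbered 44, where independent lists would share 0.651, and lower calls shared by these times numbered 13, against 3.55. Here too the common dye orientation and the shared estimate of the spread can add to the overlaps. The count of calls was 30 without 12 h Exp1 and 498 without 12 h Exp2, of which 89 were higher and 409 lower, and it was 90 without either 1 h array and 69 without either 4 h array. With array weights it was 82, after quantile normalization 777 and with equal spread 454. After the median of each run of 400 table rows was subtracted it was 118, with 88 higher and 30 lower, and with the Exp number as a block it was 67, with 47 higher and 20 lower.

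Differences between time points were tested directly. The 12 h ratio was higher than the 1 h ratio for ACTC1 by 1.87 ± 0.16 (adjusted p = 0.00449), for COA3 by 1.91 ± 0.18 (adjusted p = 0.00501), for TGFBI by 1.93 ± 0.19 (adjusted p = 0.00651), for ACTA2 by 1.80 ± 0.22 (adjusted p = 0.0211) and for ORMDL2 by 2.01 ± 0.26 (adjusted p = 0.0292). ACTA2 lay below 0 on both 1 h arrays and above 0 on both 12 h arrays. Of 15625 features tested, 18 were higher and 2 lower at 12 h than at 1 h. The 2 lower features were rows without a gene name, and the named genes chosen in that direction did not pass. For KRT15 the 1 h value averaged 2 rows and the 12 h value came from 1 of them. These genes were AGR2 (-1.80 ± 0.30), KRT15 (-1.63 ± 0.25, adjusted p = 0.0554), FOXO1 (-1.07 ± 0.20), FAM136A (-0.97 ± 0.17) and RGS4 (-0.90 ± 0.16). The count was 0 without 1 h Exp1, 32 without 1 h Exp2, 91 without 12 h Exp1 and 12 without 12 h Exp2.

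Between 1 h and 4 h no feature passed in limma, with 832 of 15860 at an unadjusted p under 0.05, where chance would give 793. THBS1 had the largest difference among the genes chosen, 2.53 ± 0.36 (adjusted p = 0.238), followed by R3HDM4, NOTCH2NLA, ACTC1 (1.19 ± 0.16) and ACTL6B (1.13 ± 0.16). In the other direction CCDC18-AS1 (-1.21), FAM53C (-1.09), UNC80 (-1.08), SMLR1 (-1.02) and MEAF6 did not pass. After quantile normalization 1 feature passed, with the compared arrays alone or array weights 0, and without 1 h Exp2 5. Between 4 h and 12 h, 2 of 15511 features passed, 1 higher and 1 lower, and both were rows without a gene name. TGFBI (2.46-fold), COA3 (1.22 ± 0.18), TPM1 (1.21 ± 0.18) and MAP4K5 (-1.23 ± 0.18) had an adjusted p of 0.138 each, and ORMDL2 (1.55 ± 0.26), UNC80, SAT1, FTL, LRFN3 and PSMB6 did not pass either. No fit with an array left out kept both calls between 4 h and 12 h.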

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

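Apart from the comparisons of time points and the correlation without features beyond 1.5-fold, the tests here were chosen after the result was seen, and the list tests on differences between times were also added then. The 12 h ratio differed from the 1 h ratio for 20 features, 18 higher and 2 lower, by a test of the difference itself. The named genes with the largest differences were ORMDL2 (2.01), TGFBI (1.93), COA3 (1.91), ACTC1 (1.87) and ACTA2 (1.80). Without 1 h Exp1 the count was 0, and without 1 h Exp2, 12 h Exp1 and 12 h Exp2 it was 32, 91 and 12. The 12 h ratio differed from the 4 h ratio for 2 features, 1 higher and 1 lower. They were row 10477 (difference 2.21) and row 6685 (difference -2.00). No fit with an array left out called both of them. Between lists, the known TGF-beta and SMAD targets were higher at 4 h than at 1 h (adjusted p = 0.0362, and 0.887 with an estimated correlation). Cytoskeletal and contractile genes were higher at 12 h than at 1 h (adjusted p = 4.24e-05, and 0.898 with an estimated correlation).

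The 327 features called lower at both 1 h and 4 h had medians of -1.04 and -0.86 on the 1 h arrays and -0.72 and -1.18 on the 4 h arrays. A dye effect of the gene would appear at every time, and the medians of these features were also below 0 at 12 h, at -0.67 on 12 h Exp1 and -0.16 on 12 h Exp2. A fall with TGF-beta1 that begins by 1 h and lasts would do the same, and the dye cannot be told apart from the treatment because no array had the dyes exchanged. To see whether the fall deepened, the 1212 features at least 1.5-fold lower on 1 h Exp1 were compared on the other arrays, and their medians were -0.64 on 1 h Exp2, -0.51 on 4 h Exp1 and -0.93 on 4 h Exp2, so the 4 h arrays lay on either side. Both explanations therefore stay open.

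Medians of the 48 runs of 400 consecutive table rows rose along the table on 12 h Exp2 from as low as -0.35 to as high as 0.27 (Spearman's rho 0.94 across runs). On 12 h Exp1 rho was 0.681. On 1 h Exp2 it was -0.791, with the widest range of run medians, between -0.39 and 0.33. A trend along the table may therefore contribute to the calls. After the run medians were subtracted, 654 of the 882 calls at 1 h, 573 of the 705 at 4 h and 103 of the 212 at 12 h were kept. For 12 h against 1 h, 13 of the 20 calls were kept. The calls at 12 h against untreated were examined further. After the run medians were subtracted, the 117 higher features kept a median of 0.84 (0.85 before) with a lower quartile of 0.59, and 76 of them were called again. Run medians reached no higher than 0.21 on 12 h Exp1 and 0.27 on 12 h Exp2. Their subtraction could thus not bring features of this size near 0, and the kept median does not test the trend. The 95 lower features went from a median of -0.79 (quartiles -0.92 and -0.70) to -0.65 (quartiles -0.82 and -0.52), with a median standard error of 0.136 before and 0.129 after, and 27 were called again. All 95 stayed below 0, but run medians no lower than -0.22 on 12 h Exp1 and -0.35 on 12 h Exp2 could hardly have turned them. Features with an unadjusted p under 0.05 went from 3564 to 2528, so the adjusted cutoff moved too, and why calls were lost in either direction was not tested. A response to 12 h of TGF-beta1 stays open for both directions.

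The array 12 h Exp2 stood apart, with correlations across features of -0.0976 to 0.167 with the 1 h and 4 h arrays, where the other arrays correlated at 0.511 to 0.735 with each other (genes are not independent replicates). Reversed dyes on that array, with its ratio not inverted to match, would give a correlation below 0 with 12 h Exp1. The correlation was 0.46, which argues against that case. With a ratio inverted to treated over untreated it could stay above 0, so the value cannot decide that case. After the run medians were subtracted, its highest correlation with a 1 h or 4 h array was 0.243, below the lowest value of 0.632 among the others, which argues against the trend as the whole source. Without features beyond 1.5-fold in the mean of the 1 h and 4 h arrays it was 0.136, against at least 0.328 among the others, so a loss of range for the strongly lower features is not the whole source either. Both 12 h arrays belong to the same group, so no biological explanation was tested, and the source stays open.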

How the results depend on the processing

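The subtraction of run medians and the crossed pairing were chosen after the data were seen. The 123 named genes that passed kept their direction under every alternative run, and the call was kept in 1518 cases and lost in 435. Several alternatives could not turn a direction, so the kept direction does not test it there. A robust prior, a fit to the arrays compared alone and a left-out array of another time do not change a mean. Array weights were equal within each time, so they do not change it either. Genes chosen for the same sign on both arrays could not turn when either was left out. For the cases in this part whose value moved, the cause was not tested, except that a left-out array leaves fewer samples, with the lone array assumed to vary like the others.

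Calls at 1 h (main 882, 17.2% higher) were 2237 with the compared arrays alone and 766 with equal spread (58 higher, 708 lower). Calls at 4 h (main 705) were 1317 with the compared arrays alone, 1905 with equal spread, 1465 after quantile normalization, 1135 with a test for each row and 1614 with array weights. Calls at 12 h (main 212) were 454 with equal spread, 777 after quantile normalization, 327 with a test for each row, 82 with array weights and 118 after run medians were subtracted. The share of higher calls at 12 h was 55.2% in the main setting (117 higher, 95 lower), 38.1% with equal spread (173 and 281), 27.7% after quantile normalization (215 and 562) and 74.6% after run medians were subtracted (88 and 30). For 4 h against 1 h (main 0), quantile normalization gave 1. For 12 h against 1 h (main 20), quantile normalization gave 41 (26 higher, 15 lower, against 18 and 2) and a test for each row gave 36. For 12 h against 4 h (main 2), the count was 1 after quantile normalization (0 higher, 1 lower), with features on all arrays and with array weights, 0 with the compared arrays alone, and 4 with a robust prior and after run medians were subtracted.

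With each array left out in turn, counts ranged from 0 to 1803 at 1 h, from 0 to 1366 at 4 h, from 30 to 498 at 12 h, from 0 to 5 for 4 h against 1 h, from 0 to 91 for 12 h against 1 h and from 0 to 2 for 12 h against 4 h. Lists called with an array left out ranged from 4 to 9 at 12 h (main 8), and stayed at 0 at 1 h and 1 at 4 h. Counts on both arrays have no value with an array left out.

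Features beyond the fold threshold on both arrays at 1 h (main 692) were 204 at 2-fold and 1842 at 1.3-fold. At 4 h (main 542) they were 95, 1501 and, with equal spread, 929. At 12 h (main 199) they were 34, 843 and, after quantile normalization, 340. The higher share at 12 h was 55.8%, and it was 79.4% at 2-fold and 41.2% at 1.3-fold. It was 42% with equal spread, 28.5% after quantile normalization and 71.9% after run medians were subtracted. At 1 h the higher share was 2.89%, with 0.49% at 2-fold and 23.9% at 1.3-fold. At 4 h (main 1) the lists called were 0 with an estimated correlation, 0 with fry and 2 with features on all arrays, and at 12 h (main 8) 0 with an estimated correlation. After run medians were subtracted 11 were called at 12 h with the preset correlation (7 higher, 4 lower). Those added were extracellular matrix genes (adjusted p = 0.00197, median -0.02), TGF-beta ligands, receptors and SMADs (0.00746) and ribosome biogenesis (0.022). Without the subtraction, an estimated correlation gave an adjusted p of 0.853 for the matrix genes and 0.905 for the ligands, receptors and SMADs.

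No sign was seen that the Exp numbers pair the arrays. Differences of Exp1 minus Exp2 correlated at -0.12 between 1 h and 4 h, -0.0209 between 1 h and 12 h and -0.3 between 4 h and 12 h. Unequal spreads of the arrays and trends along the table also enter these differences, so pairing is not excluded. With the Exp number as a block, calls were 328 at 1 h (11 higher, 317 lower), 58 at 4 h (21 and 37, against 87 and 618), 67 at 12 h (47 and 20), 0 for 4 h against 1 h, 15 for 12 h against 1 h and 1 for 12 h against 4 h, and 2 lists were called at 4 h. With the numbers crossed at 4 h, calls were 21 for 4 h against 1 h and 5 for 12 h against 4 h.

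Among the fixed genes that did not pass, signs turned as follows. In the test for each row only the weakest row of a gene was checked, so other rows of JUNB, ID2 or PMEPA1 may also have turned. After run medians were subtracted, CDKN1A was 0.0750 and ID1 -0.0223 at 1 h. With a test for each row, the weakest row of ID2 was 0.0575 at 4 h and 0.102 at 12 h. With an array left out, PMEPA1 ranged from -0.0864 to 0.181 and ID1 from -0.0245 to 0.123 at 1 h, ID1 from -0.0444 to 0.333 at 4 h and CDKN1A from -0.142 to 0.561 at 12 h. Signal over background, which sets how reliable a spot is, was not analysed here.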

Other observations

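The genes in this paragraph passed at 12 h, where the rule for named genes did not select them, and were chosen after their values were seen, so they support no shared theme. They were the transcription factors SOX4 (log2 ratio 0.94) and RUNX1 (0.67), and the signalling gene RGS5 (0.67). MARCKS (0.75), CSRP1 (0.65), S100A10 (0.71) and PTGFRN (1.08) were also higher. The protease PRSS23 was at 0.89. Lower genes were the metallothionein MT1F (-0.72), the thrombin receptor F2R (-0.72), the mitochondrial protease LONP1 (-0.61) and WFDC2 (-0.74). All of these had an adjusted p under 0.05 in limma with n = 2 arrays.

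The rows with the largest called changes at 12 h in either direction had no gene name in the annotation used here. Row 13866 was at 3.31 and row 10477 at 2.86, both above every named gene, and row 6685 and row 18470 were at -2.01 and -1.95.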
